A study of Arabidopsis thaliana with 18 samples.

How the data were processed

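RNA from Arabidopsis seeds (6 arrays) and seedlings (12 arrays) was labelled and hybridised to ATH1 arrays by the submitters. Per the labels' protocols, seeds were imbibed on agar medium in constant light and seedlings were grown in long days, and biotin-labelled cRNA was made from total RNA. The deposited table holds 1 log2 value per probe set and array, made with RMA per the submitters' processing notes, which also name affy; no versions are given in the sources used here. RMA subtracts background, makes the distribution of values alike between arrays and combines the probes of a probe set, so a change shared by most transcripts would be removed. Whether seeds and seedlings were normalized in 1 run is not given in the sources used here. No scanner files were used, so signal over background per probe set is unknown. Array medians lay between 6.70 and 6.88 log2 units. No 2 arrays held identical values (at least 99.97% of probe sets differed between any pair), and each array was counted as its own sample.

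Of 22810 probe sets, 64 AFFX controls were left out and 22746 tested. GEO's platform annotation, updated through the gene table of assembly TAIR10.1, gave exactly 1 gene for 13513 probe sets (13333 distinct loci), several for 503 and none for 8730. Probe sets with several genes or none were counted but not named. Many of the 8730 belong to genes with well-known symbols, so the named genes are weighted towards genes known only by a locus code. The array names no genome build, and no coordinates are given.

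Groups were taken from the labels. Seeds (Col-0 against prt6-1) and seedlings (6 groups in a cell-means model) were fitted apart with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity trend, no robust prior). P-values are two-sided with Benjamini-Hochberg adjustment over all tested probe sets, and a probe set was called at an adjusted p under 0.05. Every adjusted p of a gene comes from limma. Hypoxia was compared with air within each genotype, each mutant with Col-0 in each condition, the mutants with each other, and the hypoxia responses as interactions. The replicate number was not used as a block.

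Gene lists were fixed before the data were examined, 19 in number, matched by locus code with the brightest probe set standing for a gene. Measured of listed genes were 25 of 48 core hypoxia-responsive, 7 of 18 late embryogenesis, 7 of 28 photosynthesis, 5 of 17 gibberellin and germination cell wall, 4 of 15 seed storage, 4 of 19 oxidative stress and defence, 4 of 16 anthocyanin, 3 of 16 fermentation, 3 of 16 root, 3 of 16 heat shock, 3 of 10 N-end rule, 2 of 19 ethylene, 2 of 15 carbon starvation, 2 of 22 ribosomal, 1 of 15 group VII and oxygen sensing, 1 of 23 abscisic acid and 1 of 13 circadian clock. The 12 nitrate and 5 endosperm genes had no named probe set and were not analysed here. By limma, 0 of the N-end rule, ribosomal and heat shock genes were called over all probe sets in any of the 12 comparisons, in which 1740 to 4458 probe sets had an unadjusted p under 0.05. Adjusted over the list alone, 1 N-end rule gene, AT2G44420, was higher in ate1 ate2 under hypoxia relative to air. The same gene was lower in ate1 ate2 than in prt6-1 in air. Both comparisons use the same ate1 ate2 air arrays with opposite sign, so a deviation of these arrays alone could give both. Lists with at least 5 measured genes were tested with camera (preset correlation 0.01, and estimated), adjusted over the lists within a comparison. Counts were also adjusted over the list alone.

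The text names, by a rule fixed at the same time as the lists, up to 10 single-gene probe sets with the largest rise and 10 with the largest fall among calls whose replicates were separated (not asked for an interaction), up to 4 called members of each list with the largest change (or the 2 largest as values), and the mutated genes and a set of hypoxia genes where measured. Further list members, and the genes named between ate1 ate2 and prt6-1, were chosen after their values were seen.

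Overlaps and correlations of fold changes were set against lists of independent genes and against 100 simulated draws of unchanged seedling groups built from the differences between replicate arrays. The fit and camera were tested on simulated data, with noise drawn independently for each probe set. False calls from array deviations that many probe sets share are therefore not covered by the shares below. In prt6-1 against Col-0 in air, with 22746 probe sets, 62.7% of 67 simulated changes of 0.5 log2 units were called, 100% of 67 of 1 and 100% of 66 of 2, with 7.89% false calls. In seeds these shares were 17.9%, 95.5% and 98.5%, with 6.62% false calls.

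Alternatives were renormalization by quantiles, median centring, leaving out the dimmest 33.3% of probe sets, single-gene probe sets only, an intensity trend, a robust prior, array weights, 1 fit of all 18 arrays, only the compared arrays, a replicate block, stricter thresholds and leaving out each array in turn. Where an array was left out of a group of 2, the lone array was assumed to vary like the other groups. Organelle-encoded transcripts, symbol families and the difference of the prt6-1 effect between tissues were added after seeing the data.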

Results

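Transcript levels were measured on ATH1 expression arrays in Arabidopsis thaliana wild type (Col-0) and in mutants of the arginine branch of the N-end rule pathway, which marks proteins for degradation according to their N-terminal residue. The prt6-1 line carries a mutation in PRT6, the E3 ligase that recognises arginylated N termini, and ate1 ate2 is a double mutant of both arginyl transferase genes. There were 18 arrays. Seeds imbibed for 24 h were represented by 3 arrays of Col-0 and 3 of prt6-1. The labels also give 48 h of cold storage for the seed arrays and no such entry for the seedlings. Seedlings grown for 7 days were treated for 2 h in air or in argon (hypoxia), with 2 arrays for each of the 3 genotypes in each condition. The series' design text describes the replicates as independent biological experiments. The number of arrays limits the precision of every value. Array medians lay between 6.70 and 6.88 on the log2 scale.

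Arrays of 1 seedling group correlated with each other at r = 0.995 to 0.997 across probe sets, seed arrays of 1 genotype at 0.986 to 0.995, and seed with seedling arrays at 0.820 to 0.842. Col-0 seed replicate 1 stood apart from the other seed arrays. Its mean correlation with the other Col-0 seed arrays was 0.986, and its score on the second principal component of the seed arrays was 37.5, against -16.1 to -0.74 for the other 5. Probe sets of PRT6, ATE1 and ATE2 carry no gene name in the probe table used, and their levels are not analysed here. The same holds for ADH1, PDC1, SUS4, PCO1, PCO2, HB1, LBD41 and the group VII ERF genes themselves.

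The first comparison asked which transcripts hypoxia changed in wild-type seedlings. Among named probe sets AT5G10040 showed the largest rise, from 4.64 ± 0.17 in air to 10.52 ± 0.10 under hypoxia (log2, SD, n = 2 each), which is 58.9-fold (log2 fold change 5.88, SE 0.16, adjusted p = 5.13e-12). CML38, a calmodulin-like protein gene, rose 35.4-fold, from 4.95 ± 0.12 to 10.09 ± 0.06. AT3G10040, the 1 measured gene of the group VII ERF and oxygen sensing list, rose 31.5-fold, AT1G33055 29.7-fold and AT2G17850 20.3-fold. AT4G10270, AT3G23170, AT4G24110, AT3G27220 and AT5G66985 rose by log2 fold changes of 3.76 to 4.37. Of 22746 probe sets tested, 374 were higher and 104 lower under hypoxia.

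Of the 25 measured core hypoxia-responsive genes, 23 rose in Col-0 and none fell, and 24 rose when adjusted over the list alone. Their median log2 fold change was 3.23 (camera adjusted p = 1.06e-119, and adjusted p = 5.06e-05 with an estimated correlation). Of 3 measured fermentation and sucrose breakdown genes, PDC2, a pyruvate decarboxylase gene that is also in the core list, rose by 1.79 (SE 0.13, adjusted p = 6.7e-07) and AT4G17260, a lactate dehydrogenase gene, by 1.16 (SE 0.12). The gibberellin and germination cell wall list (5 measured) had a camera adjusted p of 0.0183, but adjusted p = 0.152 with an estimated correlation, and lost the call without Col-0 air replicate 2 (0.177) or Col-0 hypoxia replicate 1 (0.212). Its 1 riser was GID1A, a gibberellin receptor gene, at 0.87 (SE 0.11, adjusted p = 0.0002). STZ, a zinc-finger factor of stress responses, rose by 0.82 (SE 0.17, adjusted p = 0.021), the 1 called of 4 oxidative stress and defence transcripts. STZ was not called without Col-0 air replicate 2 (0.63) or either Col-0 hypoxia array (0.89 without replicate 1, 0.76 without replicate 2). By limma, 0 of the 7 photosynthesis, 7 late embryogenesis, 4 anthocyanin, 4 seed storage, 3 heat shock, 3 root and 2 ethylene genes were called, where 2387 of all probe sets had an unadjusted p under 0.05. Adjusted over the list alone, 1 root marker, EXPA18 at -0.61 (SE 0.16), and 1 anthocyanin gene, UF3GT at -0.64 (SE 0.17), were lower. The late embryogenesis list had a camera adjusted p of 0.287, and 0.03 without either ate1 ate2 air array.

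Among named probe sets that fell in Col-0, AT5G57760 fell by 2.01 on the log2 scale (SE 0.26, adjusted p = 0.000287), from 6.60 ± 0.36 to 4.59 ± 0.14. AT4G25250 fell by 1.29, AT5G01210 by 1.19 and AT5G62280 by 1.06. XTH33, a xyloglucan endotransglucosylase gene, fell by 0.74, and IAGLU, an auxin glucosyltransferase gene, by 0.72. The 478 calls were 243 without Col-0 hypoxia replicate 2, 281 without Col-0 air replicate 1, 316 without Col-0 hypoxia replicate 1 and 307 in 1 fit of all 18 arrays. AT5G62280 was not called without Col-0 air replicate 2 (-0.71) or either Col-0 hypoxia array (-1.07 and -1.05).

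**Figure D1:**
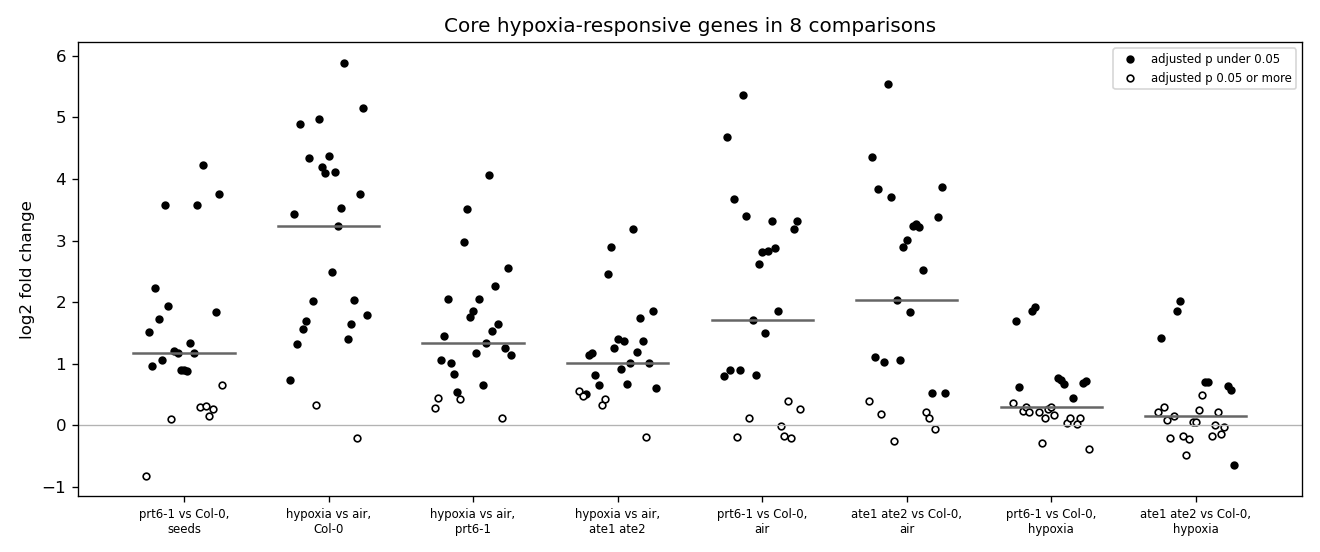
Log2 fold changes (vertical axis) of the 25 measured core hypoxia-responsive genes in 8 comparisons (horizontal axis), with filled points for an adjusted p under 0.05, open points for the others and a line at the median. The median was 3.23 for hypoxia in Col-0, 1.33 in prt6-1 and 1.01 in ate1 ate2, and 1.71 and 2.04 for prt6-1 and ate1 ate2 against Col-0 in air.

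The next comparisons asked how the mutants differed from Col-0 in air. In prt6-1 seedlings AT3G29970 was 74.0-fold higher, at 10.80 ± 0.06 against 4.59 ± 0.22 in Col-0 (SD, n = 2 each; log2 fold change 6.21, SE 0.13, adjusted p = 8.23e-13), and AT4G39675 64.1-fold higher. AT2G17850 was 41.1-fold, AT1G33055 12.7-fold and CML38 9.98-fold higher. ICL, the isocitrate lyase gene of the glyoxylate cycle, was 25.5-fold higher, at 12.32 ± 0.23 against 7.65 ± 0.53. QQS, an orphan gene that affects starch content, was 27.2-fold higher, at 10.82 ± 0.15 against 6.05 ± 0.16. In all, 495 probe sets were higher and 448 lower.

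Among the core hypoxia-responsive genes, 18 of 25 were higher in prt6-1 in air and none was lower (19 adjusted over the list alone), with a median of 1.71 (camera adjusted p = 1.24e-51, and adjusted p = 0.000604 with an estimated correlation). AT1G19530 reached 4.68 (SE 0.26), AT3G03270 3.40 and AT4G27450 3.32. AT3G10040 was higher by 1.71 (SE 0.13, adjusted p = 1.8e-06). Late embryogenesis genes went the other way, with 5 of 7 lower and none higher, also adjusted over the list alone. Their median was -1.48 (camera adjusted p = 2.33e-09, and adjusted p = 0.0273 with an estimated correlation). LEA18 fell by 2.53 (SE 0.43, adjusted p = 0.0031), from 6.74 ± 0.34 to 4.21 ± 0.12, AT3G17520 by 1.99 (SE 0.28) and AtLEA4-1 by 1.64 (SE 0.24). Of the 200 other probe sets with the largest excess in seeds over seedlings, 26 were lower and 15 higher in the same comparison. Of 4 anthocyanin and flavonoid genes, 3 fell, namely DFR, the dihydroflavonol reductase gene, by 1.66 (SE 0.23, adjusted p = 0.00071), AT4G14090 by 0.85 and UF3GT by 0.77. AT4G17260 rose by 0.67 and PPDK, pyruvate orthophosphate dikinase, by 0.52, and APL3 of the carbon starvation list, a subunit gene of ADP-glucose pyrophosphorylase, by 0.47. AT5G05200 fell by 3.47 on the log2 scale, from 10.33 ± 0.16 to 6.86 ± 0.23, and EXPB3, an expansin gene, fell by 1.63. The 943 calls were 412 without Col-0 air replicate 1, 402 without prt6-1 air replicate 2, 537 without prt6-1 air replicate 1 and 427 in 1 fit of all 18 arrays, where APL3 and AT3G15670, a late embryogenesis gene at -1.48, were not called. With only the arrays compared, APL3, PPDK and UF3GT were not called. Without Col-0 air replicate 1, AT4G14090 (-0.59), UF3GT (-0.42), PPDK (0.50) and APL3 (0.46) were not called. The call of AT4G17260 was lost without prt6-1 air replicate 2 (0.63), that of PPDK also without Col-0 air replicate 2 (0.55) or prt6-1 air replicate 1 (0.40), that of UF3GT also without either prt6-1 air array (-0.84 and -0.69), and that of APL3 without any of these 4 arrays (0.46 to 0.49). The photosynthesis list, with 0 of 7 called by limma (3600 probe sets had an unadjusted p under 0.05), had a camera adjusted p of 0.122, and 0.0179 without prt6-1 air replicate 2.

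The ate1 ate2 seedlings in air gave 475 higher and 368 lower probe sets. The share that was higher, 56.3%, was 63.9% after median centring, 65.9% in 1 fit of all 18 arrays and 68.9% with only the arrays compared. AT3G29970 was 114-fold higher at 11.42 ± 0.23 (SD, n = 2; log2 fold change 6.84, SE 0.13, adjusted p = 2.1e-13), AT4G39675 67.3-fold, AT2G17850 46.6-fold and ICL 39.7-fold. CML38 was 14.6-fold and AT1G33055 14.3-fold higher. Of the core hypoxia-responsive genes, 19 of 25 were higher and none lower (20 adjusted over the list alone), with a median of 2.04 (camera adjusted p = 1.34e-62, and adjusted p = 0.000345 with an estimated correlation). PDC2 rose by 0.53 (SE 0.13, adjusted p = 0.04) and AT4G17260 by 0.76. Of 3 root markers, EXPA7, a root hair expansin gene, rose by 0.97 (SE 0.11, adjusted p = 0.00014), while EXPA18 had a value of 0.58 (adjusted p = 0.059). Late embryogenesis genes had 2 of 7 lower (4 adjusted over the list alone), AtLEA4-1 by -1.12 and AT3G15670 by -0.89. Their camera adjusted p was 1.45e-05, but adjusted p = 0.0879 with an estimated correlation. LEA18 was at 5.48 ± 1.51 in this group. Of the 200 probe sets with the largest seed excess, 14 were lower and 22 higher. DFR fell by 0.98 (SE 0.23) and AT4G14090 by 0.64. Other falls were AT3G28220 at -1.46, AT2G25890 at -1.38 and AT2G33850 at -1.34. The 843 calls were 362 without Col-0 air replicate 1, 434 without ate1 ate2 air replicate 2, 402 in 1 fit of all 18 arrays, 379 with only the arrays compared and 544 with array weights. AT3G15670, AT4G14090 and PDC2 were called in none of these 3 fits, DFR neither in the fit of all 18 nor with array weights, AT2G25890 not in the fit of all 18 and AtLEA4-1 not with only the arrays compared. Several calls near the threshold rested on single arrays. AtLEA4-1 was not called without either Col-0 air array (-1.12 each) or ate1 ate2 air replicate 2 (-0.60). AT4G14090 was not called without Col-0 air replicate 1 (-0.38) or either ate1 ate2 air array (-0.62 and -0.66), nor was DFR (-0.63, -0.91 and -1.06), which also lost its call without either Col-0 hypoxia array (-0.98 each). AT3G15670 had -0.37 without ate1 ate2 air replicate 2, where it was not called, and -1.41 without replicate 1. It lost its call without either Col-0 air array (-0.92 and -0.86) or any hypoxia array of Col-0 or ate1 ate2 (-0.89). PDC2 lost its call without Col-0 air replicate 2 (0.32), either ate1 ate2 air array (0.44 and 0.63) or any of the 6 hypoxia arrays (0.53).

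**Figure D2:**
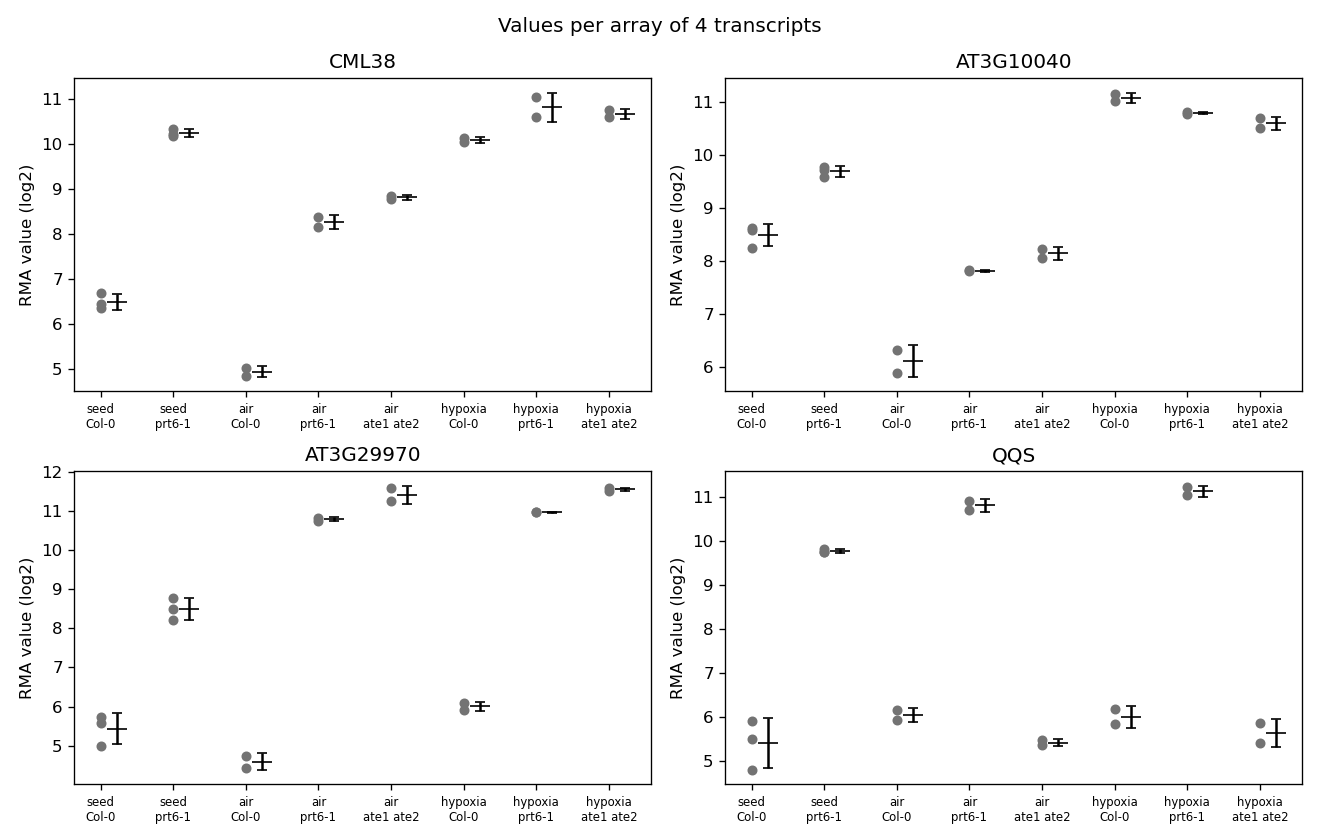
RMA values per array (points, log2, vertical axis) of CML38, AT3G10040, AT3G29970 and QQS in the 8 groups (horizontal axis), with the mean and SD beside each group (n = 3 for seeds, n = 2 for seedlings). CML38 went from 4.95 in Col-0 air to 10.09 under hypoxia and stood at 8.26 in prt6-1 and 8.82 in ate1 ate2 in air, while QQS stood at 10.82 in prt6-1 in air and at 5.41 in ate1 ate2.

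Both mutants still responded to 2 h of hypoxia. In prt6-1, 399 probe sets were higher and 528 lower, and in ate1 ate2 367 were higher and 298 lower. Of the 25 core hypoxia-responsive genes, 21 rose in prt6-1 (median 1.33, camera adjusted p = 2.49e-68, adjusted p = 0.000267 with an estimated correlation) and 20 rose in ate1 ate2 (median 1.01, camera adjusted p = 1.9e-52, adjusted p = 0.000577 with an estimated correlation), and none fell in either. Adjusted over the list alone, 22 and 23 rose. AT5G10040 rose 16.8-fold in prt6-1 and 9.11-fold in ate1 ate2, AT3G10040 7.90-fold and 5.47-fold, and CML38 5.88-fold and 3.63-fold. PDC2 rose by 1.14 in prt6-1 and by 0.62 in ate1 ate2. GID1A rose in both, by 0.88 and 0.89, and STZ by 0.88 and 1.05. Of the 3 root markers, EXPA18 and EXPA7 fell in both, EXPA18 by 1.23 in prt6-1 and by 1.21 in ate1 ate2. Its interactions with the genotype, -0.62 and -0.60, were not called (adjusted p = 0.488 and 0.513). APL3 fell by 0.69 in prt6-1. AT5G57760 fell by 2.88 and 2.66, and IAA29, an auxin response gene, fell by 1.23 in ate1 ate2. Late embryogenesis genes had a camera adjusted p of 0.0358 in ate1 ate2, with no member called, and adjusted p = 0.304 with an estimated correlation. That call was lost without ate1 ate2 hypoxia replicate 1 (0.0541) or 2 (0.0785), and without ate1 ate2 air replicate 1 the direction turned (0.36). The gibberellin list in ate1 ate2 went from 0.0747 to 0.0347 without that air array. STZ lost its call in prt6-1 without prt6-1 air replicate 1 (0.64) or either prt6-1 hypoxia array (0.92 and 0.83), and in ate1 ate2 without ate1 ate2 hypoxia replicate 2 (0.98). In ate1 ate2, PDC2 lost its call without air replicate 2 (0.52) or either hypoxia array (0.60 and 0.63), and IAA29 without air replicate 1 (-0.87) or either hypoxia array (-1.26 and -1.20). Without prt6-1 hypoxia replicate 2 the 927 calls in prt6-1 were 406, without prt6-1 air replicate 2 408, without prt6-1 hypoxia replicate 1 437, without prt6-1 air replicate 1 473 and in 1 fit of all 18 arrays 454, where APL3 was not called. The 665 calls in ate1 ate2 were 192 without ate1 ate2 hypoxia replicate 2, 351 without ate1 ate2 hypoxia replicate 1, 389 with only the arrays compared and 282 in 1 fit of all 18 arrays, where PDC2 and IAA29 were not called. Of the 927 in prt6-1, 43.0% were higher, 50.1% after median centring and 57.0% in 1 fit of all 18 arrays. Of the 665 in ate1 ate2, 55.2% were higher, 44.5% after median centring and 68.1% in 1 fit of all 18 arrays.

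The difference between the hypoxia responses was tested as an interaction. For prt6-1, 38 probe sets had a negative interaction and 0 a positive one (limma; 1846 had an unadjusted p under 0.05), and 37 of the 38 changed less under hypoxia than in Col-0. For ate1 ate2, 67 were negative and 3 positive. Of the 67, 54 changed less than in Col-0 and 13 did not, among them EXPA7, at -1.06 in ate1 ate2 and -0.24 in Col-0. Of the 25 core hypoxia-responsive genes, 14 had a negative interaction in prt6-1 (17 adjusted over the list alone, where 2 were positive) and 17 in ate1 ate2 (19 adjusted over the list alone), and the 14 and 17 changed less than in Col-0. The median interaction was -1.47 in prt6-1 (camera adjusted p = 1.84e-42, adjusted p = 0.00106 with an estimated correlation) and -1.69 in ate1 ate2 (camera adjusted p = 1.63e-68, adjusted p = 0.000265 with an estimated correlation). AT2G17850 had interactions of -3.50 (SE 0.20, adjusted p = 1.6e-07) in prt6-1 and -3.68 (SE 0.20) in ate1 ate2, AT1G33055 of -3.43 and -3.75 (SE 0.26 each), and CML38 of -2.59 and -3.29 (SE 0.20 each). AT4G39675, AT1G19530, AT4G10270, AT3G27220 and AT5G66985 were among the others in both. PDC2 had -1.18 in ate1 ate2 (SE 0.19, adjusted p = 0.011) and a value of -0.65 in prt6-1 (adjusted p = 0.34). The 2 named probe sets with a positive interaction in ate1 ate2 were AT5G48110 at 0.99 (SE 0.17, adjusted p = 0.0197) and AT4G08780 at 0.92 (SE 0.17, adjusted p = 0.0344). EXPA7 had -0.82 in ate1 ate2 (adjusted p = 0.0478), and lost its call without any 1 of the seedling arrays other than Col-0 air replicate 2 and ate1 ate2 air replicate 1 (-0.71 to -0.89). PDC2 lost its call without any 1 of the Col-0 or ate1 ate2 hypoxia arrays (-1.17 to -1.19), AT5G48110 without Col-0 air replicate 1 (0.91), Col-0 hypoxia replicate 2 (0.89) or ate1 ate2 hypoxia replicate 1 (0.91), and AT4G08780 without any 1 of 7 arrays (0.77 to 0.95), namely the first air arrays of Col-0 and ate1 ate2, all Col-0 and prt6-1 hypoxia arrays and ate1 ate2 hypoxia replicate 2. Late embryogenesis genes, none called by itself, had a camera adjusted p of 0.00454 in ate1 ate2, but adjusted p = 0.269 with an estimated correlation and 0.658 without ate1 ate2 air replicate 1. The 70 calls for ate1 ate2 were 133 without ate1 ate2 air replicate 1 and 112 without Col-0 air replicate 2. They were 42 without Col-0 air replicate 1, 46 and 41 without Col-0 hypoxia replicate 1 and 2, and 46 and 43 without ate1 ate2 hypoxia replicate 1 and 2. In 1 fit of all 18 arrays they were 44, and EXPA7, PDC2 and AT4G08780 were not called. EXPA7 and AT4G08780 were also not called with only the arrays compared or with an intensity trend, nor EXPA7 with array weights or after another quantile normalization (-0.81). The 38 calls for prt6-1 were 58 with an intensity trend.

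The mutants were also compared with Col-0 under hypoxia. AT3G10040 stood at 11.09 ± 0.10 in Col-0, 10.80 ± 0.02 in prt6-1 and 10.61 ± 0.13 in ate1 ate2 (SD, n = 2 each), and neither difference was called over all probe sets (both were lower adjusted over the group VII list alone, of which it is the 1 measured gene). Of 25 genes, 10 were higher in prt6-1 (12 adjusted over the list alone, with 1 lower; median 0.29, camera adjusted p = 3e-15, adjusted p = 0.0171 with an estimated correlation). In ate1 ate2, 7 were higher and 1 lower (9 and 2 adjusted over the list alone; median 0.15, camera adjusted p = 1.67e-06, but adjusted p = 0.0689 with an estimated correlation). AT3G03270 was higher by 1.93 in prt6-1 and 2.02 in ate1 ate2 (SE 0.12 each), and AT2G17850 by 1.86 in both (SE 0.14 each). PDC2 was lower in ate1 ate2 by -0.65 (SE 0.13, adjusted p = 0.015). AT3G29970 was higher by 4.98 in prt6-1 and 5.55 in ate1 ate2, and ICL by 4.36 in prt6-1 and 24.3-fold in ate1 ate2. Late embryogenesis genes were lower, with 5 of 7 called in prt6-1 (median -1.68, camera adjusted p = 4.12e-10, adjusted p = 0.0226 with an estimated correlation) and 4 of 7 in ate1 ate2 (median -1.48, camera adjusted p = 2.57e-11, adjusted p = 0.0321 with an estimated correlation), and 6 in each adjusted over the list alone. LEA18 fell by 3.07 in prt6-1 and by 2.52 in ate1 ate2 (SE 0.43 each). Of the 200 probe sets with the largest seed excess, 29 were lower and 12 higher in prt6-1, and 28 and 16 in ate1 ate2. Of 4 anthocyanin genes, DFR at -1.05 and AT4G14090 at -0.73 were lower in prt6-1 (3 adjusted over the list alone), as was 1 of 4 seed storage genes, AT3G01570 at -0.52, and PPDK was higher by 0.56. Without 1 array, calls were lost for DFR (any hypoxia array of Col-0 or prt6-1, -1.01 to -1.09), for AT4G14090 (Col-0 replicate 2, -0.60, or prt6-1 replicate 2, -0.67) and for PPDK (Col-0 replicate 1, 0.48, or prt6-1 replicate 2, 0.46). In ate1 ate2 they were lost for PDC2 (any hypoxia array of Col-0 or ate1 ate2, -0.64 to -0.66) and LEA18 (Col-0 hypoxia replicate 2, -2.43). In total, 353 probe sets were higher and 827 lower in prt6-1, and 252 higher and 344 lower in ate1 ate2. The share that was higher in prt6-1, 29.9%, was 40.8% after another quantile normalization and 47.4% after median centring. The 1180 calls in prt6-1 were 392 without Col-0 hypoxia replicate 2, 413 without prt6-1 hypoxia replicate 2, 540 without Col-0 hypoxia replicate 1, 612 without prt6-1 hypoxia replicate 1 and 520 in 1 fit of all 18 arrays, where AT4G14090 and AT3G01570 were not called. AT3G01570 was also not called after median centring (-0.46) or without any hypoxia array of Col-0 or prt6-1 (-0.40 to -0.63). The 596 calls in ate1 ate2 were 296 and 286 without Col-0 hypoxia replicate 1 and 2, and 310 and 229 without ate1 ate2 hypoxia replicate 1 and 2. They were 995 with only the arrays compared and 289 in 1 fit of all 18 arrays, where PDC2 and the late embryogenesis gene AT3G15670 (-1.48) were not called, and LEA18 was not called with a robust prior.

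**Figure D3:**
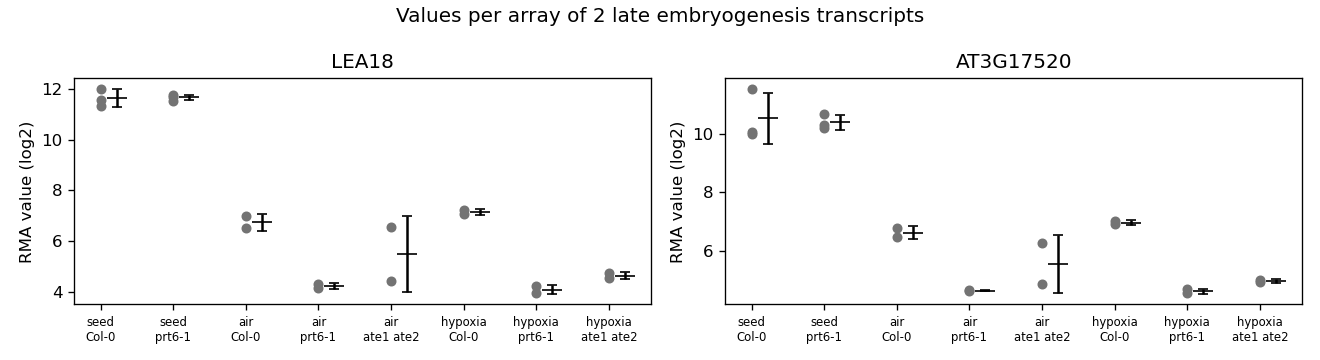
RMA values per array (points, log2, vertical axis) of LEA18 and AT3G17520 in the 8 groups (horizontal axis), with the mean and SD beside each group (n = 3 for seeds, n = 2 for seedlings). LEA18 stood at 6.74 in Col-0 air and 4.21 in prt6-1 air, and its ate1 ate2 air arrays were spread with an SD of 1.51.

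Set directly against each other, ate1 ate2 and prt6-1 differed in 29 probe sets in air (15 higher, 14 lower in ate1 ate2) and 37 under hypoxia (21 higher, 16 lower). QQS was lower in ate1 ate2 by -5.40 in air and -5.50 under hypoxia (SE 0.16 each, adjusted p = 9.47e-11 and 7.45e-11). AT5G05200 was higher by 3.53 and 3.07 (SE 0.12 each), AT1G43590 lower by -2.71 and -2.81 (SE 0.17 each), and EXPB3 higher by 1.32 and 1.70. COR15A, a cold-regulated gene, was higher by 1.43 in air and by 0.84 under hypoxia, where it lost its call without any 1 of the 6 hypoxia arrays (0.76 to 0.93). These genes were chosen after their values were seen. No core hypoxia-responsive gene was called in either (2 higher in air and 1 lower under hypoxia adjusted over the list alone), and the list's camera adjusted p of 1.21e-07 in air and 2.03e-06 under hypoxia became adjusted p = 0.0886 and 0.128 with an estimated correlation. Late embryogenesis genes, none called by itself, were higher in ate1 ate2 in air as a list (4 of 7 adjusted over the list alone, camera adjusted p = 0.000229, but adjusted p = 0.143 with an estimated correlation and 0.262 without ate1 ate2 air replicate 1). Under hypoxia their camera adjusted p was 0.486, and 0.0299 without either ate1 ate2 air array. The photosynthesis list in air had 0.0179, but adjusted p = 0.227 with an estimated correlation, 0.499 without prt6-1 air replicate 1 and 0.539 without ate1 ate2 air replicate 1. The 29 calls in air were 92 without ate1 ate2 air replicate 2, and 15 and 12 without prt6-1 air replicate 1 and 2. They were 60 with an intensity trend, 15 with only the arrays compared and 12 in 1 fit of all 18 arrays. The 37 under hypoxia were 78 without either ate1 ate2 air array and 18 without either Col-0 hypoxia array. They were 8 and 10 without prt6-1 hypoxia replicate 1 and 2, and 15 and 9 without ate1 ate2 hypoxia replicate 1 and 2. They were 87 with an intensity trend, 120 with array weights, 67 with only the arrays compared and 13 in 1 fit of all 18 arrays, where COR15A was not called, as among single-gene probe sets alone. Of the 37, 56.8% were higher, 43.5% after another quantile normalization and 35.6% after median centring.

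In seeds imbibed for 24 h, the comparison asked how prt6-1 differed from Col-0. AT4G39675 was 57.3-fold higher in prt6-1, at 12.03 ± 0.12 against 6.18 ± 0.61 (SD, n = 3 each; log2 fold change 5.84, SE 0.26, adjusted p = 2.43e-05). QQS was 20.8-fold, AT5G26200 18.7-fold, CML38 13.5-fold and AT3G29970 8.31-fold higher, and AT2G17850 was higher by 3.58 on the log2 scale. AT1G49470 was lower by 3.77 on the log2 scale, dropping from 9.59 ± 0.76 to 5.82 ± 0.19, AT2G03850 fell by 3.16, AT1G29080 by 3.06 and SAG29, a senescence-associated sugar transporter gene, by 2.07. In total 499 probe sets were higher and 435 lower.

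Of the 25 core hypoxia-responsive genes, 18 were higher in prt6-1 seeds and none lower (20 higher and 1 lower adjusted over the list alone), with a median of 1.17 (camera adjusted p = 2.8e-33, adjusted p = 0.000687 with an estimated correlation). AT4G33560 reached 3.57 (SE 0.13) and AT1G33055 2.23 (SE 0.10), and AT3G10040 1.21 (SE 0.13, adjusted p = 0.0019). Of 5 gibberellin and germination cell wall genes, EXPA8, an expansin gene, rose by 0.84 (SE 0.14, adjusted p = 0.017) and GID1A by 0.48 (SE 0.11), 3 adjusted over the list alone. That list had a camera adjusted p of 0.0116, but adjusted p = 0.0962 with an estimated correlation. GI, a circadian clock gene, rose by 1.15 (SE 0.21, adjusted p = 0.022) and EIN3, an ethylene signalling factor, by 0.67 (SE 0.10). COR47, a dehydrin gene, fell by 0.81 (SE 0.12) and STZ by 1.08 (SE 0.12). By limma, 0 of the 7 late embryogenesis, 7 photosynthesis, 4 seed storage, 4 anthocyanin, 3 fermentation, 3 root and 3 heat shock genes were called, where 4458 of all probe sets had an unadjusted p under 0.05. PAP85 had a value of 2.44 (SE 0.86, adjusted p = 0.17), and 2 seed storage genes were higher adjusted over the list alone. The 934 calls were 1554 without Col-0 seed replicate 1, the array that stood apart, 452 and 354 without Col-0 replicate 2 and 3, and 300, 331 and 359 without prt6-1 replicate 1, 2 and 3. They were 3006 in 1 fit of all 18 arrays, where 47.9% were higher against 53.4%, 1534 with an intensity trend and 1519 with array weights. GID1A was not called without any 1 array other than Col-0 replicate 1 (0.41 to 0.51), nor after another quantile normalization (0.46) or among single-gene probe sets alone. EXPA8 (0.79 to 0.86) and GI (0.93 to 1.23) were not called without Col-0 replicate 3 or any prt6-1 array, nor EIN3 without Col-0 replicate 3 or prt6-1 replicate 1 or 3 (0.62 to 0.67). Without Col-0 seed replicate 1, the late embryogenesis list, at camera adjusted p = 0.471 with all arrays, had an adjusted p of 0.00295. In the members shown per array, AT3G17520 and LEA18, prt6-1 was then not the lower genotype. AT3G17520 was at 10.06 and 10.01 in Col-0 replicates 2 and 3, and at 10.21 to 10.69 in prt6-1. LEA18 was at 11.57 and 11.35 in these Col-0 arrays, and at 11.54 to 11.76 in prt6-1. Other members are not given per array.

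The overlap of calls asked whether the transcripts changed by the mutations in air were those that hypoxia changed in Col-0. Of the 374 probe sets that rose under hypoxia in Col-0, 127 were also higher in prt6-1 in air, where independent lists of these lengths share 8.14, and 125 were higher in ate1 ate2, where they share 7.81. Among the falls, 13 and 18 were shared, against 2.05 and 1.68. Between the mutants in air, 295 were higher in both (10.3 for independent lists) and 196 lower in both (7.25). Calls in opposite directions numbered 12 for hypoxia and prt6-1 and 11 for hypoxia and ate1 ate2, against 9.63 and 8.22 for independent lists, and 1 for both mutants. These 3 pairs share both Col-0 air arrays, and part of the excess may come from that. In 100 draws of unchanged groups against shared controls, the overlap of hypoxia with either mutant was 0 in every draw, and that of both mutants was 58.0 on average and 2930 at most. All 3 pairs were drawn in the same way, so this contrast between them comes from the draws and not from the pairs. The highest overlap of any pair, 2930, lay above all 3 observed overlaps, so the draws do not exclude shared controls as their source. The draws counted calls of any size of change. With 2 control arrays, a split would leave 1 array on each side and was not made. Taken in both directions, the 140 shared calls of hypoxia and prt6-1 were 87 without Col-0 air replicate 1 and 92 without prt6-1 air replicate 2, and the 143 of hypoxia and ate1 ate2 were 90 without Col-0 air replicate 1. The 491 of both mutants were 221 without Col-0 air replicate 1, 283 without prt6-1 air replicate 2 and 308 without ate1 ate2 air replicate 2. Pairs with no shared array also overlapped, and shared controls cannot be the source of those overlaps. Of the probe sets higher in prt6-1 seeds, 85 were higher in prt6-1 seedlings in air (10.9 for independent lists) and 93 rose under hypoxia in Col-0 (8.20). Of the probe sets lower in prt6-1 seeds, 21 were lower in prt6-1 seedlings in air (8.57) and 5 fell under hypoxia in Col-0 (1.99). Calls in opposite directions numbered 35 for seeds and seedlings (19.3 for independent lists) and 13 for seeds and hypoxia (9.43). The 106 shared calls of seeds and seedlings were 68 without prt6-1 seed replicate 1, 67 without Col-0 air replicate 1, and 68 and 61 without prt6-1 air replicate 1 and 2.

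Across probe sets, which are not independent replicates, the fold changes of hypoxia in Col-0 correlated with those of prt6-1 in air at Pearson's r = 0.441 (Spearman's rho = 0.336) and with those of ate1 ate2 in air at 0.453 (0.266). Shared controls alone gave 0.458 and 0.482 on average, above both. Unchanged groups of equal size set against the same controls give such averages whatever their spread. These averages therefore cannot tell how much of the observed correlations came from shared controls. The covariances, 0.0300 and 0.0303, exceeded the simulated means of 0.00891 and 0.0108 by 0.0211 and 0.0195 but lay below the highest simulated values of 0.0432 and 0.0889. Both mutants in air correlated at 0.800 (rho 0.663, simulated mean 0.473, highest 0.969). Their covariance was 0.0577, against a simulated mean of 0.00978 and a highest value of 0.0382 for that pair. The pairs were drawn alike, and the highest simulated covariance of any pair, 0.0889, lay above 0.0577. The draws therefore do not exclude shared controls here either. With no shared array, prt6-1 in seeds correlated with prt6-1 in air at 0.121 (rho -0.00201) and with hypoxia in Col-0 at 0.195 (rho 0.0680).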

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

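The tests of a similar hypoxic level, of the late embryogenesis list under hypoxia, of the chromosome segment and of the difference between tissues, and the counts by size of change, by call in air and of seed-excess probe sets, were chosen only after the result was seen. Differences of an effect between genotypes or tissues drew attention. The hypoxia response differed from that of Col-0 in 38 probe sets in prt6-1 and 70 in ate1 ate2. For prt6-1 the 3 largest named were AT2G17850 at -3.50, AT1G33055 at -3.43 and AT1G19530 at -2.97, and for ate1 ate2 AT1G33055 at -3.75, AT2G17850 at -3.68 and CML38 at -3.29. A contrast added after seeing the data set the prt6-1 effect in seeds against that in seedlings in air, in 1 fit of all 18 arrays. It differed in 1276 probe sets, with AT5G20790 at -4.74 (lower in prt6-1 seeds, higher in prt6-1 seedlings), ICL at -4.37 and AT5G26200 at 4.22. That fit pools the spread of both tissues. Seed arrays of 1 genotype correlated at 0.986 to 0.995, and arrays of 1 seedling group at 0.995 to 0.997. Calls for prt6-1 in seeds were more numerous in that fit than with seeds fitted apart, and the 1276 was not recounted without single arrays. ICL stood at 14.33 in Col-0 and 14.63 in prt6-1 seeds, near the highest value on any array (14.66), which left no room in seeds for a rise like that in seedlings, so its difference does not compare the tissues. Seeds and seedlings also differ in age, light regime and cold storage, and which of these matters was not tested.

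Over both mutants, the 67 probe sets with a negative interaction in either had a median of -1.21, and 54 of them changed less under hypoxia in ate1 ate2 than in Col-0. A signal ceiling common to all probe sets would need mutant levels near the top of the scale, and 0 percent of the 67 lay within 1 log2 unit of the highest value of 14.66, with a median level of 10.21. A lower ceiling of single probe sets was not tested. A single stray Col-0 air array would need the pattern to shrink without it, and 94.5% of the median interaction was left in the worse case (98.4% for the 54). That transcripts already raised in air, by a median of 1.34, reached a similar hypoxic level stays open, since the median difference from Col-0 under hypoxia of 0.0725 covers members that went both ways (quartiles -0.367 and 0.658, 44.8% within 0.5). In prt6-1, 24 were called higher than in Col-0 under hypoxia, among them AT4G39675 by 3.10 and AT2G17850 by 1.86, and 15 lower, and in ate1 ate2 20 and 14.

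Of 7 late embryogenesis genes, 5 were called lower in prt6-1 seedlings in air. Stray Col-0 air arrays would not lower the list on other arrays, and its median under hypoxia was -1.68. More leftover seed material among Col-0 seedlings stays open, since 13% of the 200 other probe sets with the largest excess in seeds were called lower and 7.5% higher, against 1.97% and 2.18% of all probe sets. The median of the 200, -0.078 (quartiles -0.256 and 0.121), lay above the bound of -0.2 set beforehand, but that bound did not allow for the smaller seed excess of the set, with a median of 3.96 against 6.27 for the list. Of 4 seed storage genes none was called there (1, AT3G01570, was lower adjusted over the list alone). Their values were -0.42 for AT3G01570, -0.18 for OLEO3, 0.01 for PAP85 (limma adjusted p = 0.982) and 0.10 for AT1G03890. An effect of the genotype stays open as well.

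There were 15 probe sets that differed between ate1 ate2 and prt6-1 in the same direction in both conditions, of 8 named genes. A chromosome segment around PRT6 that differs between the lines could give such genes, and 1 of them, AT5G05200, lay within 500 table entries of PRT6 in TAIR10.1, where 0.16 were expected (one-sided Fisher exact p = 0.153), too few to decide. Among the others, EXPB3 (AT4G28250) and AT4G28260 have consecutive locus codes, with prt6-1 values against Col-0 in air of -1.63 and -1.33. A segment elsewhere than around PRT6 was not tested. A difference of the prt6-1 line present in every tissue also stays open, since 7 of the 15 were not called between prt6-1 and Col-0 in air, so that the share of the 15 called in seeds in the same direction, 26.7%, is no test of it. Of the 8 called in air, 3 were called in that direction in seeds (QQS, AT1G43590 and AT5G05200).

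For the seed comparison, the 10 splits of the 6 arrays are too few for a share under 0.05. The real split, 1 of the 10, gave 934 calls and the highest of the others gave 0.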

How the results depend on the processing

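Among the tests after the report, those of a similar hypoxic level, of the late embryogenesis list under hypoxia, of the chromosome segment, of the tissue contrast, of the organelle lists and of the symbol families were chosen only after the result was seen. Every alternative given here was fixed together with the gene lists. Of 355 results for named genes, 265 kept direction and call under every alternative run and 0 reversed. All 355 were taken from calls with all arrays, so a reversal was unlikely from the start. Single alternatives ended calls 484 times, 57 of them at an adjusted p under 0.01 and 47 in 1 fit of all 18 arrays. Among list tests outside the core hypoxia and late embryogenesis lists, 7 were weaker and 2 stronger. Where 1 of 2 arrays was left out, the lone array was assumed to vary like the other groups. Signal over background is unknown here, so which dim probe sets were above background could not be judged; leaving out the dimmest 33.3% moved no count of calls by over 1.5 times. The smaller counts at stricter thresholds follow from a higher bar. Single-gene fits had fewer probe sets and fits without an array had fewer arrays, but whether this alone gave their smaller counts was not tested. For the other alternatives, and for larger counts without an array, the cause was not tested.

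Counts are given in the order seeds, hypoxia in Col-0, prt6-1 and ate1 ate2, prt6-1 and ate1 ate2 in air, prt6-1 and ate1 ate2 under hypoxia, the interactions for prt6-1 and ate1 ate2, and ate1 ate2 against prt6-1 in air and under hypoxia; with all arrays they were 934, 478, 927, 665, 943, 843, 1180, 596, 38, 70, 29 and 37. With single-gene probe sets alone they were 446, 214, 424, 314, 451, 396, 543, 295, 18, 35, 15 and 6. In 1 fit of all 18 arrays, leaving out the interaction for prt6-1, they were 3006, 307, 454, 282, 427, 402, 520, 289, 44, 12 and 13. At an adjusted p under 0.01, again without that interaction, they were 252, 284, 428, 276, 429, 372, 479, 289, 39, 13 and 12. With an absolute log2 fold change of at least 1, without both interactions, they were 236, 151, 139, 109, 174, 143, 143, 144, 12 and 11. Leaving out 1 array gave ranges of 300 to 1554, 243 to 548, 406 to 1102, 192 to 696, 402 to 1156, 362 to 935, 392 to 1356, 229 to 699, 30 to 57, 41 to 133, 12 to 92 and 8 to 78.

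An intensity trend gave 1534 in seeds, 58 for the interaction in prt6-1, and 60 and 87 between the mutants in air and under hypoxia. Array weights gave 1519 in seeds, 544 for ate1 ate2 in air and 120 between the mutants under hypoxia. Fitting only the arrays compared gave 389 for hypoxia in ate1 ate2, 379 and 995 for ate1 ate2 in air and under hypoxia, and 15 and 67 between the mutants. With the replicate number as a block the counts were 535 in seeds and 76 between the mutants under hypoxia, and 1 named call was lost. Deviations of same-numbered arrays correlated at -0.0771 to -0.024 in seeds and -0.234 to 0.262 in seedlings, over 0.1 in 7 of 15 pairs of groups. The numbers were not taken to pair the arrays in the main fits. In seedlings an effect shared by same-numbered arrays stays open.

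With an estimated correlation, camera calls were lost for late embryogenesis genes under hypoxia in ate1 ate2 (adjusted p = 0.304), in ate1 ate2 in air (0.0879), in the interaction for ate1 ate2 (0.269) and between the mutants in air (0.143), and for core hypoxia genes in ate1 ate2 under hypoxia (0.0689) and between the mutants in air (0.0886) and under hypoxia (0.128). Another quantile normalization gave 0.0573 for the first of these. Leaving out 1 array, the late embryogenesis list ranged from 0.00295 to 0.86 in seeds, 0.03 to 0.672 for hypoxia in Col-0, 1.04e-10 to 0.36 for hypoxia in ate1 ate2 (0.36, in the other direction, without ate1 ate2 air replicate 1), 3.19e-14 to 0.658 in the interaction for ate1 ate2, 3.78e-14 to 0.262 between the mutants in air and 0.0299 to 0.861 under hypoxia. The core hypoxia list stayed under 0.05 in all 12 comparisons without any 1 array.

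With an absolute log2 fold change of at least 1, the overlaps of hypoxia in Col-0 with prt6-1 in air, of hypoxia in Col-0 with ate1 ate2 in air, of both mutants in air, of seeds with prt6-1 in air and of seeds with hypoxia in Col-0 were 51, 57, 97, 28 and 38, against 140, 143, 491, 106 and 98. Without 1 array they ranged from 87 to 195, 90 to 184, 221 to 566, 61 to 124 and 66 to 107, and the correlations from 0.401 to 0.579, 0.414 to 0.583, 0.68 to 0.847, 0.0885 to 0.137 and 0.163 to 0.205. Without the dimmest probe sets the last 2 correlations were 0.174 and 0.255.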

Other observations

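The tests of organelle lists and symbol families were chosen only after the result was seen. Of 69 measured plastid-encoded transcripts, 7 were called lower in prt6-1 than in Col-0 in air (11 adjusted over the list alone) and 62 were not called, with a median of -0.38. Relative to air, 5 were called higher under hypoxia in prt6-1 and 64 were not called, with a median of 0.27. Both comparisons use the same 2 prt6-1 air arrays with opposite sign, so a deviation of these arrays alone could give both medians. Their camera p was 5.87e-17 and 3.70e-13 with the preset correlation, and 0.104 and 0.148 with an estimated correlation. Mitochondria-encoded transcripts (22 measured) had medians of -0.07 and 0.04 in the same comparisons.

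Over 47 symbol families of at least 5 genes and 4 comparisons, the lowest camera adjusted p with an estimated correlation was 0.249. Among those with an adjusted p under 0.05 with the preset correlation, the XTH cell wall family (9 genes) had a median of 0.48 in ate1 ate2 in air (adjusted p = 0.0105, 2 called higher), and the WRKY factor family (6 genes) a median of 0.14 under hypoxia in Col-0 (adjusted p = 0.00221, 2 called higher).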
